A study of Drosophila melanogaster with 3 samples.

How the data were processed

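Chromatin from whole prepupae expressing CG3919-eGFP was sonicated, and fragments of 200 to 800 bp, per the labels, were immunoprecipitated with an antibody against GFP and sequenced in 3 biological replicates. Per the deposited provenance texts, each replicate's candidate list was derived from that replicate's alignments and 1 control file, the pooled list from all 3 replicates and the control, and the final list by thresholding on the irreproducible discovery rate (IDR, a measure of how well the ranks of replicate lists match). The candidate lists hold peaks and background regions together, so a candidate region is not a call. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each list was deposited on 2 genome builds, dm6 and dm3, which makes 10 lists, and dm6 was the main build. The 9569 reproducible peaks of dm6 are exactly the strongest 9569 of the pooled candidates, as tested on the files.

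Each list gives the position of a region, the authors' peak signal and its −log10 q-value, and the position of the summit within the region. The signal is the authors' deposited value, on a scale not given in the sources used here. It was used only to rank regions within a list. The deposited −log10 q-values were not used for ranking, because 88.1% of the reproducible peaks share the highest value of the list, 4.23. In the pooled candidate list 85.4% of regions have the same width of 436 bp, so region width says little about a binding site, and positions were taken from summits. All replicates share the control, so that features of the control common to them would appear in each list, and overlap between replicates does not exclude this.

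Annotation was taken from Ensembl release 115 (BDGP6.54), which uses dm6 coordinates, and sequence from the RefSeq genome of the same assembly. All region ends in the lists fell within the arm lengths of that reference. Transposable element entries were left out, and analysis was limited to arms 2L, 2R, 3L, 3R, 4 and X. No dm3 annotation was used here and no coordinates were converted. A TSS is the first base of any annotated transcript. A gene counted as bound when a summit lay within 500 bp of any of its TSSs, so 1 peak can count for several genes. Location classes were assigned in the order TSS window, coding exon, UTR, other exon, intron and intergenic.

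The 28 gene lists, the 22 motifs, the tests and the rule for named items were fixed before the data were examined. The rule names CG3919, the 10 strongest peaks with the gene of the nearest TSS, up to 4 members of each gene list with the strongest peak at a TSS, and the 3 motifs and 5 6-mers with the smallest p; other names are members of small counts or fill in a list, and were chosen after their values were seen. Of 376 names written in 16 of the lists, 360 matched an annotated protein-coding gene directly and 9 through an older name; 7 were absent or repeated. The other 12 lists were drawn up as name patterns.

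Overlap of replicates was compared with 100 seeded circular shifts within each arm. Shares of genes were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 28 lists, shares of sequence windows by two-sided exact McNemar tests with adjustment over the 22 motifs and separately over the 2080 6-mers, counting both strands as 1. For sequence tests peaks were thinned to 1 in 500 bp, the strongest first, and the flank side was drawn with a fixed seed. With 1 group of samples no test between groups is possible; p-values compare genes, regions or windows within 1 map, neighbouring genes can share a peak, and the spread between the 3 replicates is given beside them from the strongest 9569 candidates of each. With 3 replicates no sample was tested as an outlier. Wilson intervals were computed at 95%. Numbers were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

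The tests were checked on simulated data. Among 13945 genes with lists of 50, the gene list test called 32 of 40 lists in which 50% of genes were bound, 40 of 40 with 75%, and 4 of 480 unchanged lists. Many real lists were smaller, down to 14 genes, and power for those was not simulated. A smaller list that did not pass can therefore still differ from other genes. The rate of false calls was not estimated for lists whose members are neighbours or share a peak. A DRE planted in random windows was called in 10 of 10 simulations and 0 of 210 other motif tests were called. The simulated summit and flank windows had equal base composition, and DRE was planted at a far higher share than real summits showed. This check therefore does not cover calls caused by a difference in base composition, nor power for small excesses. Alternatives covered the TSS window, the 4784 strongest peaks, summit or midpoint, the overlap required, the gene background, the control windows for motifs, the dm3 lists, and each replicate left out in turn. For peak counts, gene shares, arms and motifs, leaving out a replicate kept the reproducible peaks matched in both other replicates, 7508 to 7669 peaks. Those peaks and their summits still derive from all replicates. Such values show a stricter filter, not a map made without that replicate. Expression data, other tagged proteins and the control's own regions were not analysed here.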

Results

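Chromatin immunoprecipitation followed by sequencing was carried out on whole prepupae of Drosophila melanogaster, with males and females pooled. The animals came from a transgenic line that expresses the CG3919 protein with green fluorescent protein (eGFP) at its C terminus, and the tagged protein was recovered with an antibody against GFP. The prepupa is the stage at the onset of metamorphosis, when pulses of the steroid hormone ecdysone replace larval tissues with those of the adult. There was 1 group of 3 biological replicates and 1 control file for each genome build, so there was no second condition to compare with and each comparison below is made within the genome. For every replicate the deposited list held 30000 candidate regions, and the pooled replicates gave a further 30000. From these lists the authors derived 1 set of 9569 reproducible peaks on the dm6 build. The number of sequenced reads is unknown from peak lists, so no read depth is given, and the intervals printed here cover counting error only. Ranks follow the authors' peak signal within a list, where rank 1 is the strongest.

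Strong regions were largely shared between the 3 replicates. The strongest 9569 candidates of a pair of replicates overlapped by 1 bp or more for 79.9% of regions between replicates 1 and 2, 82.2% between 1 and 3, and 83.0% between 2 and 3. Circular shifts of the regions along their chromosome arms gave means of 4.92% to 5.02% over 100 shifts for each pair, with 6.93% as the highest. When regions had to share 50% of both lengths, the mean shared share was 71.2% instead of 81.7% ± 1.64 (SD, n = 3 pairs). The reproducible set is the strongest part of the pool of these same replicates, so its support in each of them is high by construction, and the values that follow only describe it. Of the reproducible peaks, 97.0% had an overlapping candidate region in replicate 1, 98.8% in replicate 2 and 99.6% in replicate 3. Restricted to the 9569 strongest candidates of each replicate, the share was 88.5% ± 0.920 (SD, n = 3), and 6965 peaks (72.8%) were matched in all 3 replicates. Spearman's rho between the ranks of these peaks was 0.815 for replicates 1 and 2, 0.867 for 1 and 3, and 0.828 for 2 and 3, across peaks, which are not independent replicates. The reproducible peaks had a median width of 436 bp, ranged from 109 to 1272 bp, merged into 8975 separate regions and covered 3.34 Mb, which is 2.49% of the 6 main chromosome arms.

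The strongest peak lay on X at 2703649 to 2704110 (dm6), with its summit 24 bp upstream of the transcription start site (TSS) of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter. It ranked 1, 1 and 2 in replicates 1, 2 and 3. The second was on 3L at 19590399 to 19590840, 102 bp upstream of CG14100 (FBgn0036889), with a mean replicate rank of 2.67 ± 2.08 (SD, n = 3). Rank 3 in every list belonged to a peak on 2L at 480552 to 481367, inside an intron of ush. The summit was 1368 bp upstream of the nearest TSS, that of cbt (FBgn0043364), a zinc finger transcription factor gene. The fourth peak, on 2L at 6612414 to 6612976, was in an intron of CG11050 (FBgn0031836), 1038 bp downstream of its nearest TSS. The fifth, on 3R at 31404439 to 31404884, sat 84 bp upstream of a TSS of PNPase (FBgn0039846), the gene of a mitochondrial polynucleotide phosphorylase, and within the PNPase gene. The sixth, on 2L at 13835258 to 13835687, was within 500 bp of the TSSs of both CenG1A (FBgn0028509) and mRpS23, a mitochondrial ribosomal protein gene. The others of the 10 strongest were on 3R at 11760813 to 11761311, in an intron of the protein kinase gene Lk6 (FBgn0017581); on 3R at 17704187 to 17704639, in an exon of lncRNA:CR46035 (FBgn0267702) within the osa gene; on 3R at 29214181 to 29214662, 111 bp upstream of lncRNA:CR31044 (FBgn0051044); and on 3L at 22878674 to 22879126, 107 bp upstream of a TSS of Chro (FBgn0044324), which encodes the chromodomain protein Chromator. The peak at Chro was also within 500 bp of a TSS of Ssl1.

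Reproducible summits lay near a TSS more often than other candidates or shifted peaks did, and seldom in coding exons. Of the 9569 reproducible summits, 3403 (35.6%, 95% Wilson interval 34.6% to 36.5%) lay within 500 bp of an annotated TSS, against 3241 of 18657 pooled candidate regions (17.4%) that no reproducible peak overlapped. The odds ratio was 2.63 (two-sided Fisher's exact test, p = 1.05e-245). Circular shifts of the reproducible peaks put 13.5% ± 0.588 (SD over 100 shifts) within 500 bp of a TSS, with 15.1% as the highest. In the strongest 9569 candidates of each replicate the share was 33.1%, 39.2% and 37.5%, a mean of 36.6% ± 3.14 (SD, n = 3). A further 42.7% of reproducible summits lay in introns, against 48.1% of the other candidates and 39.4% of shifted peaks, and 18.4% were intergenic, against 27.9% of the other candidates and 27.4% of shifted peaks. Coding exons away from a TSS held 1.01% of reproducible summits, while they held 3.20% of the other candidates and 13.8% of shifted peaks. The other candidates were thus also far below the shifted peaks there, so a low share in coding exons is not particular to the reproducible peaks. Summits near a TSS were mostly on its upstream side: 2492 of the 3403 (73.2%) lay upstream, with a median position of -74 bp.

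**Figure D1:**
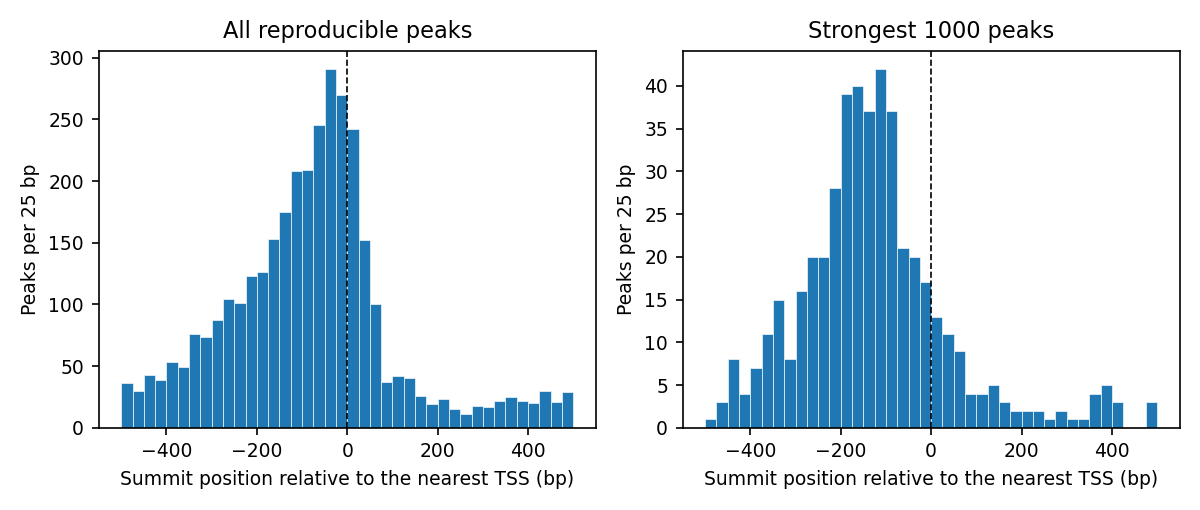
Positions of summits within 500 bp of the nearest TSS, in bins of 25 bp, with upstream positions negative, for all reproducible peaks (left) and for the strongest 1000 (right). The dashed line marks the TSS; the median position was -74 bp over all 3403 such peaks and -141 bp over the 469 among the strongest 1000.

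Shares of genes with a peak at a TSS are given by gene class, with no test between classes. A reproducible summit lay within 500 bp of a TSS for 3217 of 13945 protein-coding genes on the main arms (23.1%, 95% Wilson interval 22.4% to 23.8%). The share was 12.1% (11.0% to 13.3%) for 3261 genes annotated as other non-coding RNAs, 13.8% (10.3% to 18.2%) for 290 tRNA genes and 7.81% (5.16% to 11.6%) for 269 snoRNA genes. For pseudogenes it was 5.22% (3.14% to 8.58%), or 14 of 268. Among 32 snRNA genes, 3 had a peak: snRNA:U1:95Ca, snRNA:7SKa and snRNA:U4:39B, which were named after their values were seen. None of 99 rRNA genes had one, with an upper Wilson bound of 3.74% that takes the genes as independent. Since the aligner is not given, it is unknown how reads from repeated copies were placed. The lack of a peak there does not show a lack of binding. Window and threshold set these shares, and the protein-coding share was 18.5% with a window of 250 bp and 26.9% with 1000 bp. With 1000 bp the tRNA share was 23.8% and the snoRNA share 22.3%, and without replicate 2 they were 7.59% and 4.46%. For gene shares here and below, without a replicate means that only reproducible peaks matched in both others were kept. This stricter filter cannot raise a share. The share of other non-coding RNAs was 6.72% with 250 bp and 20.1% with 1000 bp, and that of pseudogenes was 2.99% with 250 bp and 3.36% without replicate 2 or 3.

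Genes for the proteins of the cytosolic ribosome had peaks more often than the other protein-coding genes. They are 1 of the 28 gene lists fixed before the data were examined. Apart from an interval set beside that of respiratory chain genes below, the lists were not compared with each other. A peak lay at a TSS of 64 of 86 ribosomal protein genes (74.4%, 95% Wilson interval 64.3% to 82.5%), against 22.8% of the other protein-coding genes, with an odds ratio of 9.88 (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 1.91e-22). In the replicate lists the share was 74.0% ± 6.61 (SD, n = 3). The strongest of these peaks were at RpS27 on 3R, 13 bp upstream of the TSS, with a mean replicate rank of 216 ± 175 (SD, n = 3); RpL7 on 2L, 44 bp upstream, with a mean rank of 249 ± 50.1; RpL24 on 2L, 15 bp downstream, with a mean rank of 536 ± 226; and RpL32 on 3R, 173 bp upstream, with a mean rank of 626 ± 362. Ribosomal proteins of the mitochondrion had some of the strongest peaks, at mRpS23 (mean replicate rank 6.33 ± 0.577), mRpL41 (16.0 ± 2.65) and mRpS10 (18.7 ± 3.51), but as a list their share, 22 of 73 (30.1%), did not pass the test (adjusted p = 0.351, two-sided Fisher's exact test). A comparison with random gene sets matched on gene span and number of TSSs was added after the data were seen. Matching used classes of both, and classes of TSS number alone where too few genes shared both. In it the mitochondrial list did pass, with 30.1% against a mean of 11.7% (permutation test, adjusted p = 0.00140 over the 28 lists). When a peak counted only for its nearest TSS, the mitochondrial share was 9.59%, below the 18.2% of other genes (Fisher's exact test, adjusted p = 0.206). The peak at mRpS23, for example, is nearer to CenG1A.

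Genes of the ecdysone hierarchy and genes of insulator and promoter-binding proteins were the other lists with more peaks than the remaining genes. Of 28 ecdysone response genes, 18 (64.3%, 45.8% to 79.3%) had a peak at a TSS, with an odds ratio of 6.03 (adjusted p = 2.63e-05, two-sided Fisher's exact test) and a replicate share of 63.1% ± 2.06 (SD, n = 3). Among them were E23, an ABC transporter gene, 207 bp upstream of the TSS (mean replicate rank 167 ± 40.0), Ldh (476 ± 204), the nuclear receptor gene Eip75B (495 ± 159) and Hr78 (1962 ± 698). EcR and usp, whose products form the ecdysone receptor, and ftz-f1, br, Eip74EF, Eip78C, Hr3 and Hr4 also had a peak. Of 20 insulator and promoter factor genes, 12 (60.0%, 38.7% to 78.1%) had one, with an odds ratio of 5.02 (adjusted p = 0.00197, two-sided Fisher's exact test) and a share of 55.0% in each of the 3 replicate lists. The strongest were at Chro (9.67 ± 2.08), Cp190 (237 ± 17.6), the GAGA factor gene Trl (599 ± 75.5) and M1BP (1398 ± 397). Among genes that had any pooled candidate region at a TSS, neither list passed. The ecdysone genes had a peak in 18 of 23 (78.3% against 65.1%), with an odds ratio of 1.93 (95% interval 0.690 to 6.67, two-sided Fisher's exact test, adjusted p = 0.5). The insulator and promoter factors had one in 12 of 13 (92.3% against 65.0%), with an odds ratio of 6.45 (0.952 to 276, two-sided Fisher's exact test, adjusted p = 0.169), so too few genes were left to tell. The ecdysone call also ended against matched random gene sets (permutation test, adjusted p = 0.130). There the insulator and promoter factors still passed (60.0% against a mean of 29.7%, permutation test, adjusted p = 0.0261). Their call ended when a peak counted only for its nearest TSS (40.0%, Fisher's exact test, adjusted p = 0.0752), where that of the ecdysone genes held.

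Chemoreceptor, cuticle protein, midgut digestive and salivary glue and puff genes had fewer peaks than the other genes. Peaks were at a TSS of 2 of 179 chemoreceptor genes (1.12%, adjusted p = 9.08e-17, two-sided Fisher's exact test), Gr77a and Ir67c, and of 2 of 122 cuticle protein genes (1.64%, adjusted p = 1.24e-10), Cpr12A and Cpr51A. The cuticle share was 9.02% with a window of 1000 bp, 0.82% without replicate 2 and 0% without replicate 1 or 3, and the chemoreceptor share was 2.79% with 1000 bp and 0.559% without any 1 replicate, with both calls kept. One maltase gene, Mal-A5 on 2R, was the exception among 43 midgut digestive genes (2.33%, adjusted p = 0.00197, two-sided Fisher's exact test), with a strong peak 143 bp upstream of its TSS (mean replicate rank 246 ± 22.8, SD, n = 3). No peak was found at any of 22 salivary glue and puff 71E genes, which allows a share of up to 14.9% by the Wilson interval (adjusted p = 0.0178, two-sided Fisher's exact test). The midgut call ended with the 4784 strongest peaks (2.33% against 14.4%, Fisher's exact test, adjusted p = 0.0753), among genes with a candidate region (33.3% against 65.1%, adjusted p = 0.5) and against matched gene sets (2.33% against a mean of 11.3%, permutation test, adjusted p = 0.174). That of the glue and puff genes held in only 2 of 9 other settings, while their share was 0% in all 9.

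The other 20 lists did not pass the test, with adjusted p of 0.106 or more (two-sided Fisher's exact test). Heat shock genes had a peak in 9 of 22 (40.9%, adjusted p = 0.181, two-sided Fisher's exact test), led by the small heat shock protein gene Hsp27, which ranked 11 in all 3 replicates, and by Hsp83 (370 ± 134) and Hsp26 (613 ± 117). Autophagy genes had 9 of 20 (45%, Fisher's exact test, adjusted p = 0.106), with Atg2 (807 ± 269) and Atg17 (923 ± 519) the strongest, and their share was 25% without replicate 2 and without replicate 3. Polycomb and Trithorax group genes had 10 of 29 (34.5%), among them ph-p (ranks 28, 39 and 53 in replicates 1, 2 and 3) and brm (250 ± 179). Shares for the remaining machinery of the cell were 11 of 34 aminoacyl-tRNA synthetases (32.4%), 12 of 44 translation initiation factors (27.3%), with eIF6 at 40.0 ± 13.5, 11 of 40 TFIID and Mediator subunits (27.5%), 8 of 32 proteasome subunits (25%), 17 of 84 genes of oxidative phosphorylation (20.2%), 6 of 31 DNA replication genes (19.4%) and 2 of 23 spliceosomal proteins (8.70%), snRNP-U1-C and snf. Developmental and tissue genes had 9 of 36 homeotic and patterning regulators (25%), with tin at 481 ± 218, 5 of 15 cell death genes (33.3%; hid at 392 ± 47.6, Dcp-1, Diap1, Buffy and Debcl), 5 of 20 fat body genes (25%; Apoltp, bmm, FASN1, Lsd-2 and Lsd-1), 6 of 28 muscle genes (21.4%), 5 of 28 neuronal genes (17.9%; elav at 261 ± 36.8, futsch, Csp, Syx1A and ple), 3 of 17 hemocyte genes (17.6%), ush, PPO3 and crq, 2 of 19 germline genes (10.5%), orb and bgcn, and 1 of 23 spermatocyte genes (4.35%), Mst87F. No spermatocyte gene had a peak when 1 replicate was left out, whichever it was, and the list passed without replicate 1 only (Fisher's exact test, adjusted p = 0.0498, 0.0565 and 0.0845 without replicates 1, 2 and 3). Keeping only peaks matched in both other replicates lowered the share by 1.5 times or more in several of the 28 lists. This stricter filter cannot raise a share, so the falls do not by themselves show dependence on 1 replicate. Among these lists, cell death genes were at 20% without replicate 1 and 13.3% without replicate 2. Translation initiation factors were at 15.9% without replicate 2, and hemocyte genes at 11.8% without replicate 2 or 3. None of 14 antimicrobial peptide genes had a peak, which allows up to 21.5% by the Wilson interval. Neuronal genes had fewer peaks than matched random gene sets (17.9% against a mean of 46.3%, permutation test, adjusted p = 0.00784).

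**Figure D2:**
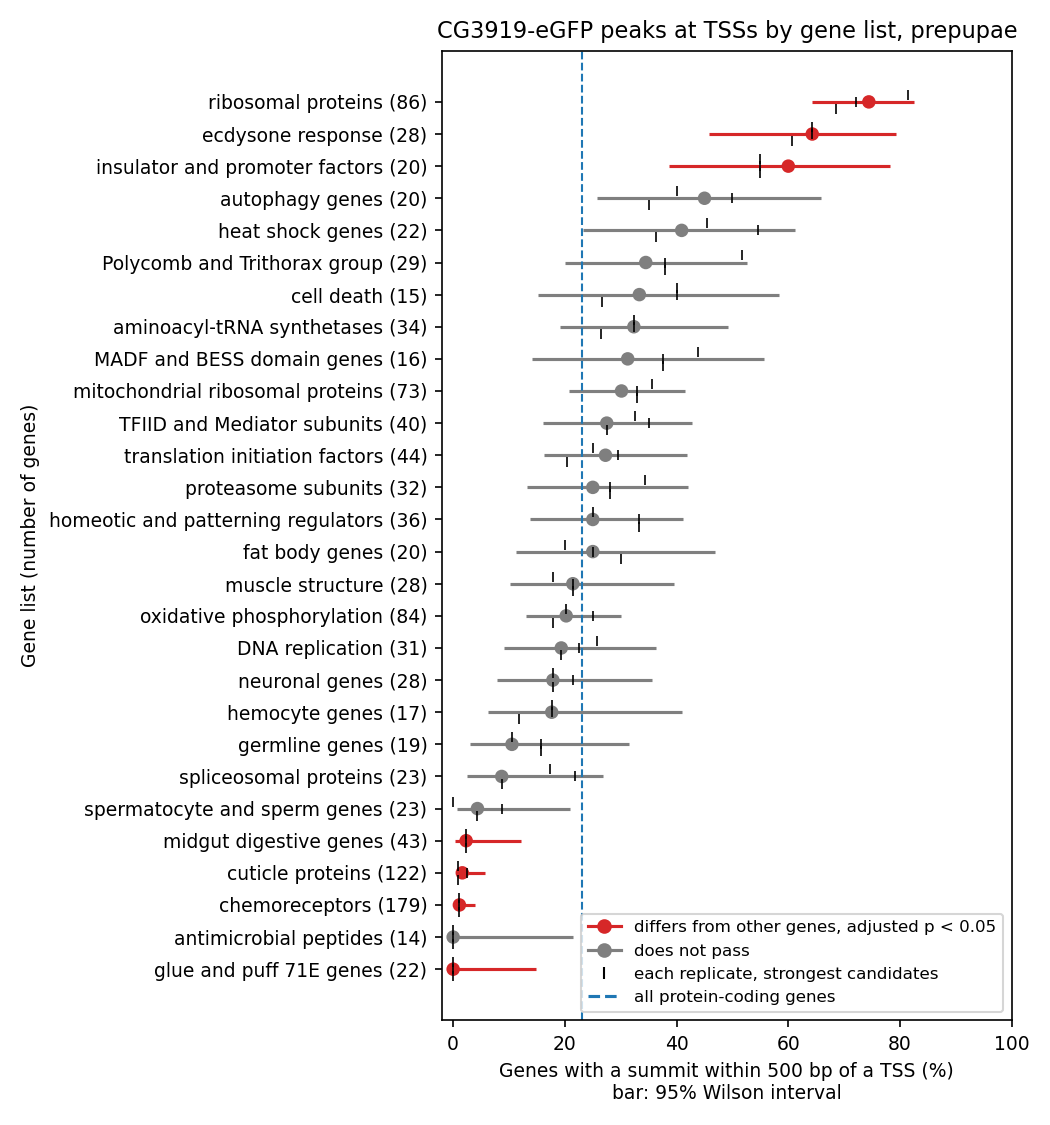
Share of the genes of each list with a reproducible summit within 500 bp of a TSS (points, in %, with 95% Wilson intervals as bars), red where the list differs from the other protein-coding genes after adjustment; ticks are the 3 replicates' own strongest 9569 candidates and the dashed line is the share of all protein-coding genes, 23.1%. Ribosomal protein genes are at 74.4%, and chemoreceptor, cuticle, midgut and glue genes are at 2.33% or below.

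The gene of the tagged protein itself had a peak at its TSS. The line is transgenic, and whether extra copies of this locus add to the signal was not examined here. The peak alone therefore does not show that the protein binds its own gene. CG3919 (FBgn0036423) lies on 3L at 14410626 to 14412732 (dm6), on the plus strand. A reproducible peak at 14410222 to 14410651 reached into its 5 prime end, with the summit 128 bp upstream of its TSS and inside the overlapping gene lncRNA:CR45233 on the other strand. This peak was rank 611 of the 9569. The summit was at the same base, 14410498, in all 3 replicates, where the region ranked 504, 608 and 619, a mean of 577 ± 63.5 (SD, n = 3). In replicate 1 that region was narrower and ended 19 bp before the gene. Replicate 3 had a further candidate inside the gene at 14411039 to 14411149, at rank 3530. CG3919 is placed here in a list of 16 genes with MADF or BESS domains, which are DNA-binding and protein interaction domains. Of these, 5 (31.2%) had a peak at a TSS, which did not pass the test (adjusted p = 0.604, two-sided Fisher's exact test): brwl (mean replicate rank 90.7 ± 4.04), hng3 (272 ± 59.0), CG3919, Coop (1860 ± 15.6) and CG3386.

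**Figure D3:**
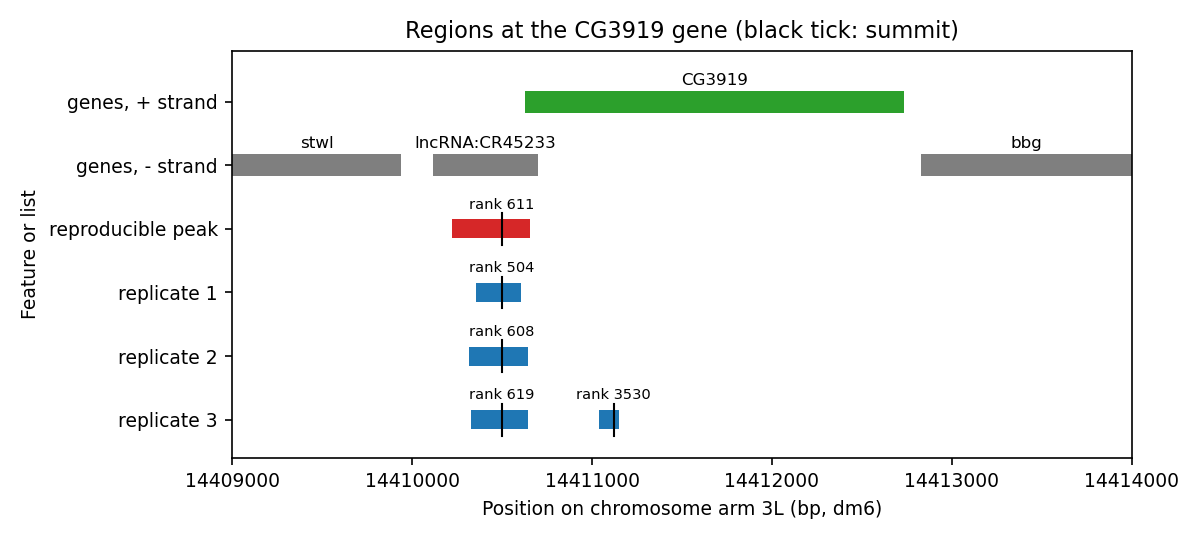
Map of 3L around CG3919 (dm6 position in bp on the horizontal axis), with genes of each strand, the reproducible peak and the candidate regions of the 3 replicates as bars to scale, black ticks at summits and the rank of each region in its list. The summit at 14410498 is shared by the reproducible peak and all 3 replicates.

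Peaks were scarce on chromosome 4, and X did not differ in density from the large autosomal arms taken as 1 group. There were 72.1 peaks per Mb on 2L, 66.3 on 2R, 77.7 on 3L, 70.6 on 3R and 73.7 on X, and differences among the large arms were not tested one by one. The density on X was 1.03 times that of the 4 large autosomal arms (95% interval 0.974 to 1.08, exact binomial test, two-sided, p = 0.322), and 1.01 ± 0.0619 in the replicate lists (SD, n = 3). A peak was at a TSS of 24.1% of X-linked and 22.99% of autosomal protein-coding genes (two-sided Fisher's exact test, p = 0.247). Chromosome 4 had 11 peaks, or 8.16 per Mb, a density 0.114 times that of the large autosomal arms (0.0567 to 0.204, exact binomial test, p = 5.09e-28) and 0.137 ± 0.0418 times in the replicate lists (SD, n = 3). Of its 80 protein-coding genes, 4 (5%) had a peak at a TSS (two-sided Fisher's exact test against the autosomal arms, p = 2.29e-05). These were RpS3A, Mpv17, PlexA and Sox102F, named after their values were seen. When peaks had to be matched in replicates 1 and 2 alone, the X density ratio passed the exact binomial test (1.07, p = 0.0296), as did the share of X-linked genes, 19.5% against 17.6% (Fisher's exact test, p = 0.0312).

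DNA at the summits was AT-rich and enriched for short AT-rich words, with some core promoter elements. GC content in the window of 50 bp on either side of the summit was 36.6%, against 44.6% in a window of equal width centred 300 bp away, and the values for the replicate lists were 36.8% ± 0.263 and 44.6% ± 0.215 (SD, n = 3). Among the strongest 1000 peaks it was 32.2% at the summit. Over 8901 peaks at least 500 bp apart, 600 of the 2080 6-mers were more frequent at summits than in flanks and 1011 were less frequent (exact McNemar test, two-sided, Benjamini-Hochberg adjusted). Of the 600, 534 had 4 or more A or T bases. The 5 with the smallest p were AAATAT, in 27.8% of summit and 13.9% of flank windows (exact McNemar test, adjusted p = 2.23e-107), ATATTA (17.0% and 6.61%), AATATA (20.1% and 8.91%), TTAAAA (26.8% and 14.0%) and ATTTAA (23.8% and 11.8%). Against dinucleotide shuffles of the same windows the counts were 321 and 546, and TTAAAA did not pass (26.8% against 26.5%, exact McNemar test, adjusted p = 0.666).

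Of the 22 listed motifs, 5 were more frequent at summits and 7 less frequent. The TATA box was in 6.40% of summit and 3.24% of flank windows (adjusted p = 3.06e-22, exact McNemar test), and in 6.47% ± 0.0471 and 3.36% ± 0.163 in the replicate lists (SD, n = 3). The DNA replication-related element (DRE, TATCGATA), bound by Dref and BEAF-32, was in 0.944% and 0.371% (exact McNemar test, adjusted p = 7.92e-06). Motif 1, the element of M1BP, was in 0.483% and 0.112%, core promoter motif 7 in 4.85% and 3.33%, and the su(Hw) core in 0.461% and 0.112%. The su(Hw) call ended without replicate 1, that is with only peaks matched in both other replicates (0.397% against 0.184%, exact McNemar test, adjusted p = 0.0505). Only 7061 windows were left there and flank sides were assigned anew, so the loss need not come from the replicate. At peaks over 500 bp from a TSS neither DRE (0.155% and 0.138%, exact McNemar test, adjusted p = 1) nor motif 7 (2.62% and 2.89%, adjusted p = 0.522) passed. Of the motifs less frequent at summits, the smallest p were those of the GC box, in 1.75% and 4.98% (adjusted p = 2.21e-32, exact McNemar test), and the CA repeat, in 1.52% and 4.08% (adjusted p = 4.52e-25). The E-boxes CACGTG and CAGCTG, the GAGA element, the Adf1-like triplet repeat and the Ftz-f1 element (0.112% and 0.449%) were also less frequent at summits. The GAGA call ended with a window of 100 bp on either side of the summit (exact McNemar test, adjusted p = 0.681). That of Ftz-f1 ended against matched candidate regions (0.119% against 0.202%, Fisher's exact test, adjusted p = 0.377) and at peaks over 500 bp from a TSS (exact McNemar test, adjusted p = 0.100), and its summit share was 0.0566% without replicate 1. The ecdysone receptor element was in 1 summit window and 3 flank windows, too few to show a difference. Against other candidate regions matched on distance to a TSS, 1 listed motif was still more frequent, the TATA box (6.42% against 4.46%, adjusted p = 1.67e-07, two-sided Fisher's exact test); DRE, Motif 1, motif 7 and su(Hw) no longer passed. Against shuffles of the same windows that keep dinucleotides, the TATA box did not pass (6.40% against 6.50%, exact McNemar test, adjusted p = 0.880), and DRE did (0.944% against 0.0899%, adjusted p = 3.04e-16). The direction turned there for the GC box, the CA repeat, the GAGA element, the E-box CAGCTG and the Adf1-like repeat, which were more frequent at summits than in the shuffles, and the call of the E-box CACGTG ended (0.697% against 0.944%, exact McNemar test, adjusted p = 0.129).

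**Figure D4:**
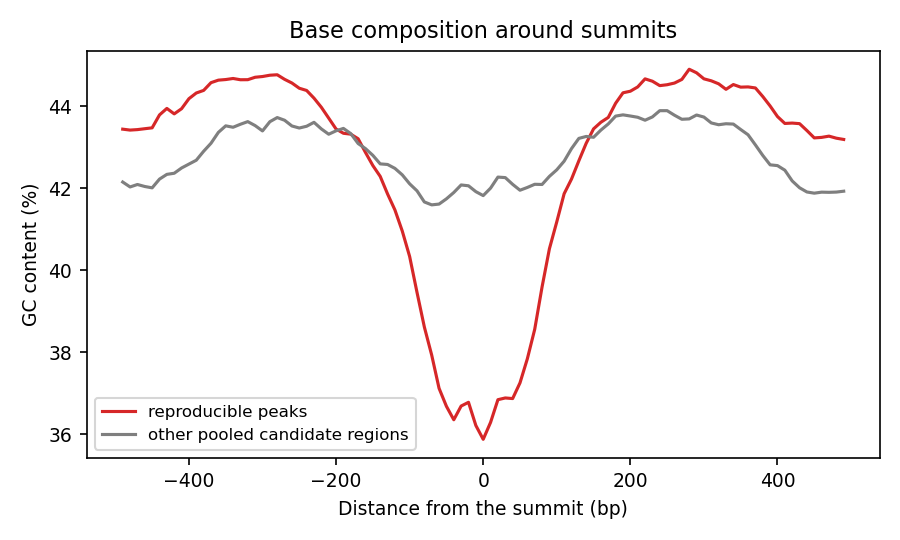
Mean GC content (%, averaged over 21 bp) by distance from the summit in bp, for the 9569 reproducible peaks (red) and the 18657 pooled candidate regions that none of them overlaps (grey). The red line dips at the summit, where the windows of 50 bp on either side averaged 36.6% against 42.0% for the other candidates.

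The authors' lists on the older dm3 build gave similar shares of peaks by chromosome arm. The dm3 set held 9125 reproducible peaks, 444 fewer than on dm6, and 2L, 2R, 3L, 3R and X each had fewer peaks on dm3, by 65 to 121. Chromosome 4 had 7 peaks on dm3 and 11 on dm6. The share of peaks on any 1 arm differed by at most 0.174 percentage points between builds. No peak signal value of a dm6 list was also in its dm3 list, compared exactly as deposited, and at equal rank the dm3 signal of the reproducible peaks was lower by a median of 2.08% in the authors' deposited values. On dm3 the mean overlap between replicates was 81.5% and the mean rho 0.839.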

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

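The dm3 lists hold regions on other sequences of that build: heterochromatin scaffolds, unplaced sequence and, in replicate 2, the mitochondrial genome. They were not analysed further, and no control regions were analysed here to set beside them. The dm3 reproducible set has 6 such peaks, which are part of its total of 9125, 4 of them on the collection of unplaced sequences called Uextra, 1 on 3LHet and 1 on XHet. The pooled candidates have 21. Among the replicates, replicate 1 has 67 such candidates, of which 23 lie on 3LHet and 21 on 2RHet, replicate 2 has 15 and replicate 3 has 19. The peak on XHet has rank 3191 of the dm3 reproducible set, the best rank of these 6. No biological explanation was tested for them.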

How the results depend on the processing

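The stricter set of strongest peaks holds 4784 by construction. Requiring 50% reciprocal overlap gave 71.2% shared regions. With 1 replicate left out only 1 pair remains, so shared regions (79.9% to 83.0%) and rho (0.815 to 0.867) are the values of single pairs given above. The share of protein-coding genes with a peak was 18.5% at 250 bp, 26.9% at 1000 bp, 14.4% with the 4784 strongest, and 17.8% to 19.6% without 1 replicate, settings chosen after the data were seen that change the number of peaks or the window. The promoter share kept its direction and its side of the threshold in every alternative with a test. Among genes with a candidate region, 1 list was higher (ribosomal proteins) and 2 lower instead of 3 and 4, and with the 4784 strongest 2 were lower; fewer genes or peaks enter those tests. Ribosomal protein, chemoreceptor and cuticle genes kept their call in 9 of 9 other settings. The X density ratio was between 0.987 and 1.07 without 1 replicate, and passed without replicate 3. The share of X-linked genes passed at 1000 bp (28.8%), and was between 18.9% and 19.5% without 1 replicate, passing without replicate 3. The cause was not tested.

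Against matched candidate regions 1 listed motif was higher. Against dinucleotide shuffles, a control added after the data were seen, 12 listed motifs were higher and 1 lower, and 321 6-mers were higher and 546 lower. Motifs reversed there, from fewer than in flanks to more than in shuffles: the E-box CAGCTG (3.70% at summits), GAGA (2.25%), the CA repeat (1.52%), the Adf1-like repeat (3.68%) and the GC box (1.75%); shuffles share the base composition of the summit, and flanks do not. The CG3919 locus was not run on dm3, which has no annotation here. Read depth is unknown from peak lists, and no limit that needs it is given. No paired analysis was possible because there is 1 group.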

Other observations

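The motif division, long genes, summit positions and absent regions below were chosen and tested after the data were seen, as were the tests of respiratory chain genes and of single 6-mers. For each listed motif, summit windows were divided into those near and far from a TSS. DRE was in 2.40% of 3127 summit windows within 500 bp of a TSS and in 0.156% of 5774 others (two-sided Fisher's exact test, adjusted p = 4.46e-24 over the 22 motifs), motif 7 in 8.99% and 2.62% (adjusted p = 6.10e-37) and Motif 1 in 1.15% and 0.121% (adjusted p = 3.78e-10). The su(Hw) core was less frequent near a TSS, 0.224% against 0.589% (Fisher's exact test, adjusted p = 0.0303), and the TATA box did not pass, 5.66% against 6.81% (adjusted p = 0.0625). Other motifs were also more frequent near a TSS, among them GAGA (3.90% against 1.35%, Fisher's exact test, adjusted p = 4.18e-13) and the E-box CAGCTG (5.44% against 2.75%, adjusted p = 1.96e-09). Promoter sequence alone can give such differences. Against candidate regions matched on distance to a TSS, DRE did not pass (0.856% against 0.642%, Fisher's exact test, adjusted p = 0.313). Words outside the AT-rich group also stood above both flanks and dinucleotide shuffles: CACTGA was in 6.80% of summit windows, 3.86% of flanks and 3.24% of shuffles, and ACACTG in 7.21%, 4.13% and 3.55%, among 107 6-mers above both.

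Some long genes held more peaks than shifted peaks placed there. Among 1013 protein-coding genes of at least 20 kb, 17 held more peaks than in any of 100 circular shifts, and 317 held none. By chance alone, a single shift set against the others exceeded all of them in 8.23 ± 2.82 genes (SD over 100 shifts), with 15 as the highest, so many of the 17 could be chance. On 2R, sbb held 31 peaks in 79.1 kb against a mean of 4.99 under the shifts and 22 at most, and shn held 21 against at most 12. On X, Mnt held 17 in 29.9 kb against at most 11, and on 3R tara held 17 against at most 13. Tet, with 29 against at most 32, and mam, with 22 against at most 23, did not exceed the shifts. The replicate lists gave 29.7 ± 1.53 regions for sbb and 22.0 ± 1.00 for shn (SD, n = 3).

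Stronger peaks sat farther upstream of the TSS. The median summit position was -141 bp for 469 of the strongest 1000 peaks near a TSS and -61 bp for the 2934 remaining ones (permutation test over 100000 permutations, two-sided, p = 1e-05, the smallest they can give). In the replicate lists these medians were -140 ± 12.4 bp and -60.5 ± 13.6 bp (SD, n = 3).

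Some strong peaks had no candidate region in 1 replicate. Of the 2000 strongest reproducible peaks, 28 had none in replicate 1, all 28 of them present in both others, 15 had none in replicate 2 and 4 had none in replicate 3. The strongest without a region in replicate 1 was rank 377. The genes Rpn3, ThrRS, Taf4 and Atg18a, among the strongest of their lists, are among those absent from replicate 1.

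Ribosomal protein genes had peaks more often than other genes, and the values argue against some technical sources. Among genes with any candidate region at a TSS, the odds ratio stayed at 8.72 (95% interval 3.24 to 33.0), so entry into the candidate list alone does not account for the share. The reproducible peaks are the strongest of these same candidates, so this test only asks which candidates rank higher. It cannot limit recovery that grows with how open or active a promoter is. Random sets matched on number of TSSs and, where enough genes were available, on gene span never reached the share of the list. The highest was 39.5% (one-sided permutation p = 0.0001, the smallest 10000 sets can give). Respiratory chain genes, taken as another widely and strongly expressed set, had 20.2% with an upper bound of 30.04%, below the lower bound of 64.3% for the ribosomal list. Expression was not analysed here, so this comparison does not exclude promoter activity as a source. What stays open is unspecific recovery at the most open or most transcribed promoters, since control regions and other tagged proteins were not analysed here. No biological explanation was tested because the design has 1 group.

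For ecdysone response genes the picture is weaker. Among genes with a candidate region the odds ratio was 1.93 (95% interval 0.690 to 6.67), so promoters that enter the candidate list for any reason are a candidate explanation. Gene span and number of TSSs alone argue less well: matched sets averaged 44.1%, and one-sided p was 0.0186 for a share of 64.3%. That p did not pass as a two-sided value adjusted over the 28 lists (0.130). No biological explanation was tested.

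The AT-rich 6-mers at summits could reflect base composition alone. Dinucleotide shuffles of the same windows left 4 of the 5 named 6-mers more frequent at summits. AAATAT was 8.77 percentage points above them (27.8% against 19.0%), more than the dinucleotide content of the whole window gives. ATATTA (17.0% against 15.8%, exact McNemar test, adjusted p = 0.0450) and ATTTAA (23.8% against 21.7%) were close to their shuffles. Flank windows were not compared with their own shuffles. The GC box, less frequent at summits than in flanks, was also above the shuffles. An excess over shuffles alone therefore does not show enrichment at summits. TTAAAA was 0.371 points above its shuffles (adjusted p = 0.666, exact McNemar test), so for that word composition is enough. A bias of equal size in all candidate regions is argued against by the smaller drop in GC from flank to summit outside the reproducible set. There it was -1.56 percentage points against -7.99, a smaller drop in every replicate list. A bias that grows with the recovered signal is not addressed, since the drop was -13.4 points in the strongest 1000 peaks. What stays open is sequence preference of the protein against a feature of the recovered fragments, and no biological explanation was tested.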
